A study of Danio rerio with 18 samples.

How the data were processed

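RiboMeth-seq reads ribose methylation of rRNA from the positions at which alkali-broken fragments end: a methyl group on the 2'-oxygen protects the neighbouring bond, so a methylated nucleotide is under-represented among read ends. It was measured in 14 libraries of zebrafish RNA from 5 stages: 3 of unfertilized egg, 3 of 32-cell embryos, 3 of 12-somite embryos, 3 of protruding-mouth larvae and 2 of adult tail. Replicates were biological, per the labels. The series also holds 4 small-RNA samples from early embryos, which were not used here.

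RNA was fragmented by alkali, fragments of 20 to 40 nt were ligated with a modified Arabidopsis tRNA ligase and the libraries were sequenced on an Ion Proton instrument, per the labels' protocols. Reads were trimmed with cutadapt 2.0 and mapped with Bowtie2 2.3.4.1, per the submitters' processing notes. Egg, 32-cell and 12-somite libraries were mapped to the early (maternal) rRNA and protruding-mouth and adult libraries to the late (somatic) rRNA, per the file headers. The stage sheets hold the deposited count of read 5' ends and of 5' and 3' ends together at each rRNA position, without normalization. The deposited RiboMeth-seq value of each library is a fraction on a scale of 0 to 1. In the overview the authors give it as a score, as the mean and standard deviation over the libraries of a stage.

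The arithmetic behind the deposited fraction was worked out from the values. It equals 1 minus the ends at the position over the mean of the weighted means of 6 positions on each side, with weights from 1 for the nearest to 0.5 for the farthest, and values below 0 set to 0. Computed this way from the counts, it differed from the deposited value by at most 5.00e-13. For adult tail, the library numbers over the columns do not match the sample titles. The 2 columns of 5' and 3' read ends together were used as columns of the stage, and 10 other columns of values per library were not used. The scores of the 2 adult libraries, called A and B, were computed from the counts.

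Some stage means of the overview were corrected for a barcode effect, per the file headers. Comparison with the stage sheets showed 25 such means at 11 sites, which were rebuilt by changing 28 library values. In the 4 stages from egg to protruding-mouth, scores from 5' read ends alone were put in for some libraries to match each mean. All these means were rebuilt this way, with 24 values replaced, so which libraries the authors corrected is inferred. The 4 corrected values of adult libraries were derived by arithmetic from the authors' mean. The comparisons below use the uncorrected scores, and the corrected scores served as an alternative.

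The authors list 98 sites, 35 in 18S, 60 in 28S and 3 in 5.8S rRNA. Sites carry the authors' names, which follow human numbering. Positions are given in the early and late rRNA as the files number them, from 1. Early and late rRNA were aligned with Biopython 1.88, and 15 sites had a difference between them within 6 positions. A site needed a mean of at least 10 read ends over its 12 flanking positions in every library. The lowest such mean was 32.25, so 0 sites were left out.

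The scores were compared with limma 3.58.1 in R 4.3.3 without transformation, with stage means as the model and the spread shared by all 14 libraries. Each of 5 pairs of stages was tested with a moderated contrast, and all 5 stages with a moderated F test. The Benjamini-Hochberg adjustment ran over the 98 sites within each comparison, with a threshold of 0.05. Called sites were compared between subunits with Fisher's exact test and between nucleotides with a permutation test of 100000 resamples, both two-sided. Stage means were classed as full (at least 0.75), partial or weak (under 0.25). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

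The samples, the tests, the lists of sites and most alternatives were fixed before the data were examined. The sites named were those past the threshold, up to 12 rises and 12 falls for adult tail against egg, up to 6 and 6 for consecutive stages and 10 for all stages. Added to these were the sites of 3 fixed lists: sites known as partial in human or mouse, the A-loop of the large subunit, and 5.8S sites. Any other site named was chosen after its values were seen.

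The alternatives fixed in advance were the logit of the score limited to 0.01 to 0.99, 2 unweighted flanking positions on each side, a coverage minimum of 50 or none, a change of at least 0.1, limma with trend and robust on, libraries centred on their median, a quasi-binomial model of the counts, the 2 stages compared alone, 4 stages without adult tail, the replicate number as a block, class limits of 0.8 and 0.2, and leaving out each library of the comparison. The check of replicate numbers correlated the libraries' deviations from their stage means across sites. Between 32-cell, 12-somite and protruding-mouth, same-numbered libraries deviated together, with r from 0.199 to 0.588 in 9 of 9 pairs, and each library correlated best with its own number. This was worked out by pairs of stages only after the calls with the replicate block had been seen. Pooled over 4 stages, 9 of 18 same-numbered pairs had r over 0.1, and 0 of 12 libraries correlated best with their own number in every other stage. Between 12-somite and protruding-mouth same-numbered libraries carry the same barcode. The egg libraries did not pair by their own number, with r over 0.1 in 0 of 3 pairs with each stage. In another order, chosen after the correlations were seen, egg libraries 1, 2 and 3 had r from 0.193 to 0.637 with libraries 2, 3 and 1 of these stages, in 9 of 9 pairs. The replicate block on 4 stages therefore sets the egg libraries with other partners, and no block in that order was fitted.

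Chosen after seeing the data were the barcode-corrected scores, alone, on the logit scale or with barcode as a block, barcode as a block alone, 5' read ends only, scores not limited at 0, the sites without any barcode correction, the replicate block within the 3 stages from 32-cell to protruding-mouth, and leaving out a library of a stage outside the comparison.

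The libraries carry 7 barcodes. Egg and 32-cell libraries share none with the later stages, so barcode as a block was fitted within egg and 32-cell and within the 3 later stages.

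The fit was tested on simulated data, in 50 simulations of 98 sites. For 32-cell against egg it recovered 62.0% of changes of 0.1, 84.4% of changes of 0.2 and 93.4% of changes of 0.4. For adult tail against egg these shares were 53.4%, 81.4% and 93.4%, and for adult tail against protruding-mouth 50.6%, 82.6% and 95.0%. False calls averaged 0.82 to 1.26 per simulation where changes were simulated, and calls averaged 0.04 to 0.06 with no change simulated. For each comparison, every size was set at 500 sites over the 50 simulations, mostly downward, with noise drawn independently per library. Each simulation changed more sites than the main fit called in the data, which eases the adjustment. Real libraries also deviate together, so these shares may overstate what the data could recover.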

Results

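Ribose methylation was measured at 98 rRNA sites in zebrafish from the unfertilized egg to the adult, as the fish replace the early ribosomes laid down in the egg by late ones. Most sites were highly methylated at every stage. The median over sites, averaged over libraries, was 0.948 ± 0.0129 (SD, n = 3) in egg, 0.941 ± 0.00121 (n = 3) at 32-cell, 0.933 ± 0.00467 (n = 3) at 12-somite, 0.934 ± 0.0147 (n = 3) at protruding-mouth and 0.943 ± 0.00219 (n = 2) in adult tail. A score of 1 stands for full methylation and 0 for none.

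The 14 libraries held between 1494730 read ends, in adult library A, and 15358081, in egg library 1. The third 12-somite library held 4408072 read ends, of which 10.4% fell on 10 positions. The mean over the flanking positions of a site was at least 32.25 read ends in every library.

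By stage means, 92 sites were fully, 4 partially and 2 weakly methylated in egg. The weak ones were 28S-Cm3916 and 28S-Am4560. At 32-cell the classes held 87, 11 and 0 sites, and at 12-somite 86, 12 and 0. They held 87, 10 and 1 at protruding-mouth, where the weak site was 18S-Um354, and 92, 6 and 0 in adult tail. No test was applied to these counts. Without egg library 1 or egg library 3 the egg had 7 partial sites. Without egg library 1 it had 1 weak site, and 32-cell had 1 weak site without its library 1. Protruding-mouth had 0 weak sites without its library 1 or its library 3.

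How the adult tail differed from the egg was asked first, since these stages stand at the ends of the series. The stage means differed by at least 0.1 at 20 of 98 sites, and 3 sites passed the threshold. 28S-Cm3916, almost unmethylated in egg, was highly methylated in adult tail, and 28S-Gm2817 also rose. 18S-Um287 fell from near full methylation. The other 95 sites did not pass the threshold.

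In limma, 3 of 98 sites passed, 2 higher and 1 lower in adult tail, against 12 at an unadjusted p under 0.05. The quasi-binomial model called 3 sites, of which 2 were shared: it called 18S-Um287 and 28S-Gm2817 but not 28S-Cm3916. 28S-Cm3916 (position 3197 in early and 3085 in late rRNA) scored 0.0193 ± 0.0335 (SD, n = 3) in egg and 0.901 ± 0.00446 (n = 2) in adult tail. The change was 0.882 (SE 0.122, limma adjusted p 0.00142), and its flanking positions held at least 523.1 read ends on average. 28S-Gm2817 (2265 and 2249) went from 0.777 ± 0.0334 (n = 3) to 0.963 ± 0.0189 (n = 2), a change of 0.186 (SE 0.0362, limma adjusted p 0.0129). 18S-Um287 (334 and 297) went from 0.984 ± 0.00642 (n = 3) to 0.879 ± 0.00188 (n = 2), a change of -0.106 (SE 0.0151, limma adjusted p 0.00142). At each of the 3 sites both adult libraries lay outside the range of the 3 egg libraries, as they did at uncalled sites such as 18S-Am1678. The 3 sites were picked by this comparison, so this adds no support. With barcode-corrected scores 5 sites passed, the same 3 with 18S-Gm436 (0.366, limma adjusted p 0.00115) and 18S-Am1678 (-0.256, limma adjusted p 0.00185), 2 sites chosen after their values were seen. With uncorrected scores their limma adjusted p was 0.422 and 0.127. At 18S-Gm436 egg library 2 and adult library B were corrected, the latter from 0.476 to 0.959. At 18S-Am1678 only 32-cell library 2 was corrected, so the change was -0.256 with either score. 28S-Gm2817 did not pass without egg library 3 (limma adjusted p 0.0609), adult library A (0.143) or adult library B (0.0539). The 2 stages have different rRNA references and share no barcode, so barcode as a block could not be fitted for them. 28S-Cm3916 and 18S-Um287 have a sequence difference between these references within 6 positions, while 28S-Gm2817 has none. At 18S-Um287 reference and stage were not told apart in this comparison. The adult libraries were all of tail, so age and body part cannot be told apart at any site.

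**Figure D1:**
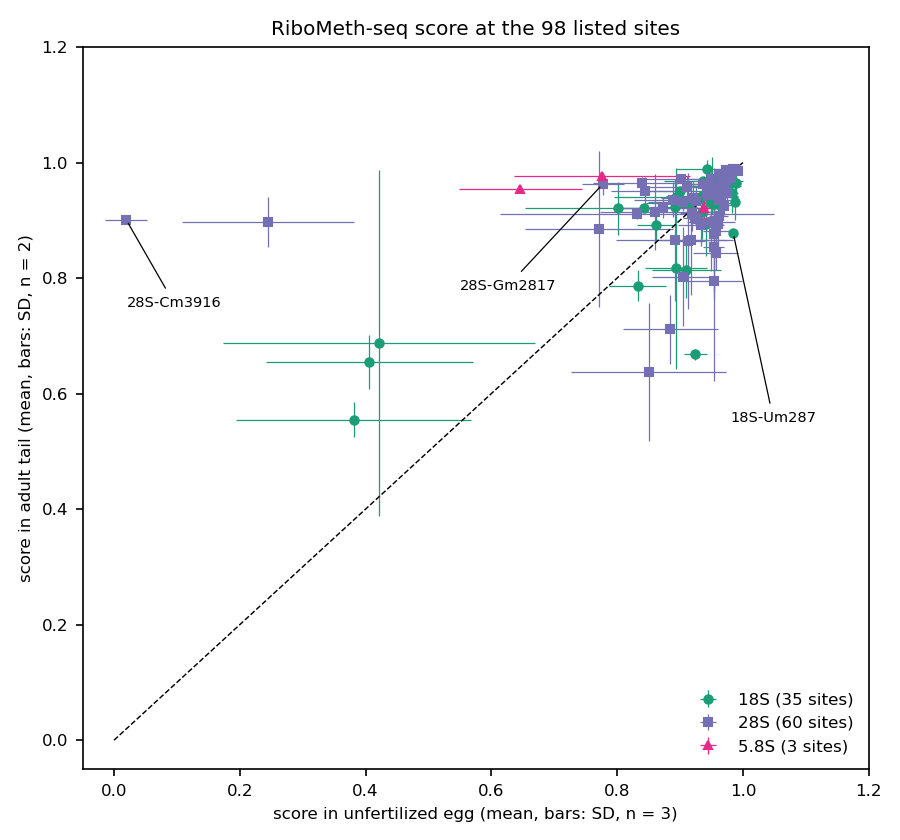
Score in adult tail (vertical, 0 to 1) against score in unfertilized egg (horizontal, 0 to 1) for the 98 sites, as means with SD bars (2 adult and 3 egg libraries), marked by rRNA. Most sites sit near the top right; 28S-Cm3916 goes from 0.0193 to 0.901.

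Where in the ribosome the called sites lay was compared next. Both subunits held called sites, and so did C, G and U. In adult tail against egg, 1 of 35 sites of the small subunit and 2 of 63 of the large subunit were called (Fisher's exact p 1). The same counts held for all 5 stages (Fisher's exact p 1). Among A, C, G and U sites 0, 1, 1 and 1 were called over all 5 stages (permutation p 0.703). With 3 called sites, all 3 in the large subunit would give a Fisher's exact p of 0.551, so the test could not show a concentration there.

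Over all 5 stages, 28S-Cm3916, 28S-Gm2817 and 18S-Um287 differed. They were the same 3 sites that separated adult tail from egg, so age and body part cannot be told apart here either. 28S-Cm3916 was higher at each later stage mean, and 18S-Um287 was lower.

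The moderated F test of limma called 3 sites, against 12 at an unadjusted p under 0.05, and the quasi-binomial model called 4. Each of the 3 had a limma adjusted p of 0.0109. 28S-Cm3916 scored 0.364 ± 0.149 (SD, n = 3) at 32-cell, 0.429 ± 0.257 (n = 3) at 12-somite and 0.733 ± 0.0616 (n = 3) at protruding-mouth. 28S-Gm2817 scored 0.695 ± 0.0567 (n = 3), 0.734 ± 0.0445 (n = 3) and 0.808 ± 0.0352 (n = 3) at these stages. 18S-Um287 scored 0.967 ± 0.00316 (n = 3), 0.965 ± 0.0268 (n = 3) and 0.943 ± 0.0135 (n = 3). The count was 0 without adult library A, without adult library B and with 4 stages, and 6 with barcode-corrected scores. With 5' read ends only, in 4 stages, it was 3, of which 1 was shared, 28S-Cm3916.

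**Figure D2:**
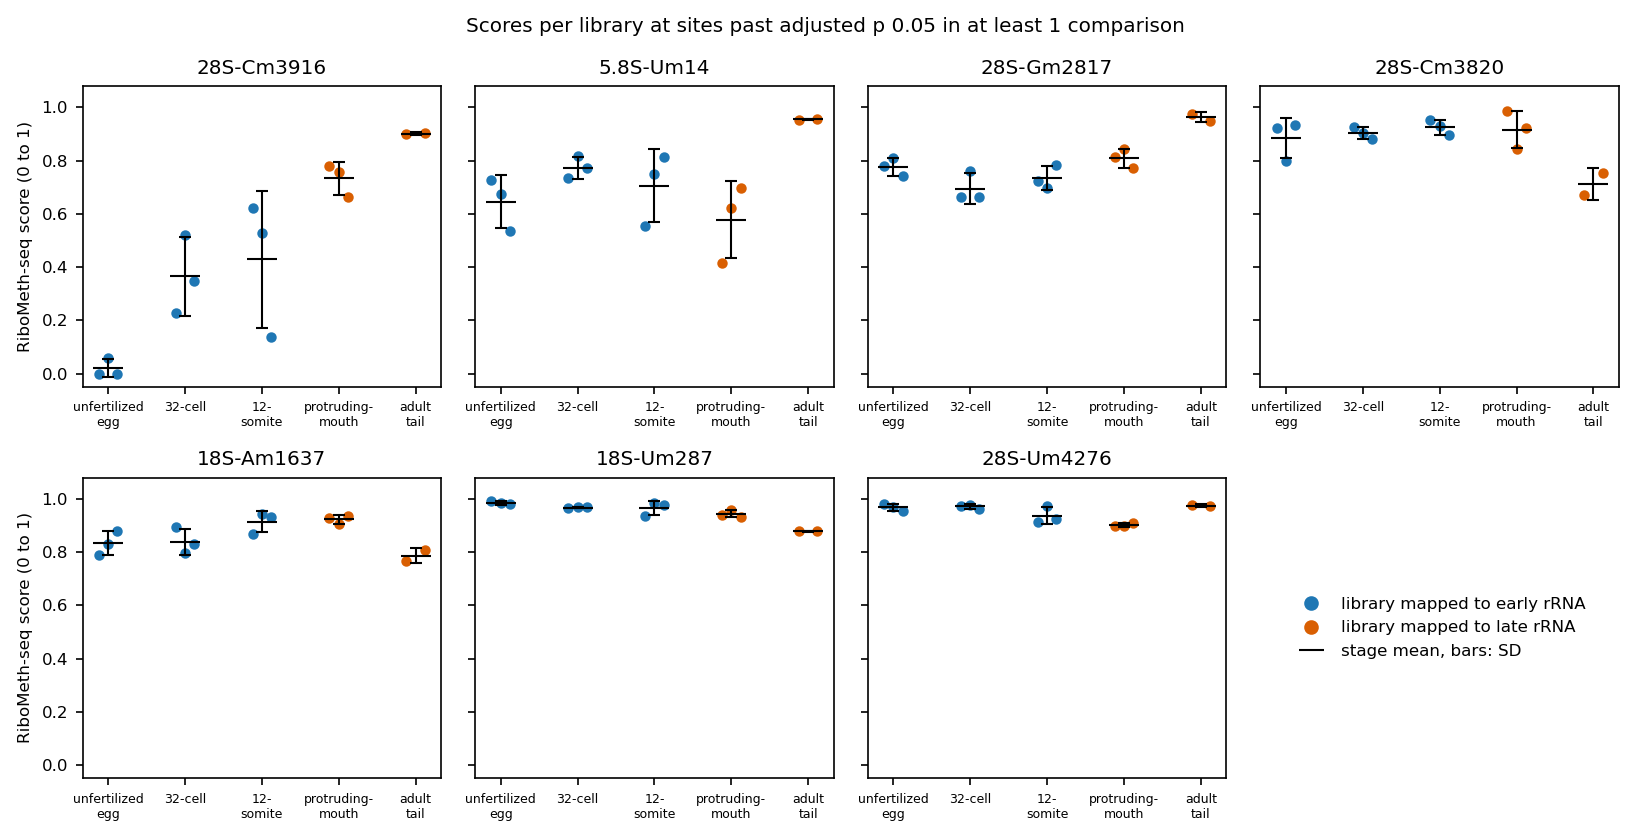
Score per library (vertical, 0 to 1) at each stage for the sites past an adjusted p of 0.05 in at least 1 comparison, with stage means and SD bars; colour marks the rRNA reference of the library. 28S-Cm3916 has its stage mean at 0.0193 in egg and 0.901 in adult tail.

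From egg to 32-cell embryos, across fertilization and the first cleavages, no site passed the threshold. The stages share a reference and some barcodes.

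limma called 0 of 98 sites, with 5 at an unadjusted p under 0.05, and the quasi-binomial model called 0, with 10 at an unadjusted p under 0.05. At 88 sites the stage means differed by less than 0.1. The differences ran from -0.363, at 18S-Cm346, to 0.345, at 28S-Cm3916, both named after their values were seen. In 5' read ends only, 18S-Cm346 had means of 0.966 ± 0.0283 (SD, n = 3) and 0.964 ± 0.00836 (n = 3), and 28S-Cm3916 of 0 ± 0 (n = 3) and 0.383 ± 0.183 (n = 3). Without 32-cell library 1, 1 site passed, 18S-Cm346, and without 12-somite library 3, 1 site passed, 28S-Cm3916. With barcode as a block the count was 0, and with barcode-corrected scores and this block it was 1, 18S-Cm346. On the logit scale it was 1, 28S-Cm3916.

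From 32-cell to 12-somite embryos, again no site passed the threshold. Both stages were mapped to the early rRNA. Most stage means lay close together.

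limma called 0 of 98 sites, with 5 at an unadjusted p under 0.05, and the quasi-binomial model called 0, with 9 at an unadjusted p under 0.05. At 92 sites the stage means differed by less than 0.1. With barcode-corrected scores 1 site passed, 18S-Gm509 (555 in early and 519 in late rRNA), which scored 0.808 ± 0.0272 (SD, n = 3) and 0.966 ± 0.0117 (n = 3), a change of 0.158 (limma adjusted p 0.0351 with corrected and 0.761 with uncorrected scores). That site was chosen after its values were seen. Only egg library 2 was corrected there, outside this comparison, so the change was 0.158 with either score. The stages share no barcode, so barcode and stage cannot be told apart.

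From 12-somite embryos to protruding-mouth larvae no site passed the threshold either. Here the rRNA reference changes from early to late, together with the stage. Barcodes are shared.

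limma called 0 of 98 sites, with 6 at an unadjusted p under 0.05, and the quasi-binomial model called 0, with 7 at an unadjusted p under 0.05. At 91 sites the stage means differed by less than 0.1, and the differences ran from -0.221 to 0.304. With barcode as a block the count was also 0.

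From protruding-mouth larvae to adult tail, 6 sites passed the threshold, 3 higher and 3 lower, with the late rRNA as the reference of both. Age and body part change together here and cannot be told apart. 5.8S-Um14, 28S-Gm2817 and 28S-Um4276 rose. 18S-Um287, 18S-Am1637 and 28S-Cm3820 fell. The number called varied from 0 to 8 with the processing, and none of the falls passed on the logit scale, with 2 flanking positions or with barcode as a block.

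In limma 6 of 98 sites passed, against 13 at an unadjusted p under 0.05, and the quasi-binomial model called 0, with 5 at an unadjusted p under 0.05. The largest change among the called sites was at 5.8S-Um14 (position 14 in both rRNAs), from 0.577 ± 0.145 (SD, n = 3) to 0.955 ± 0.000722 (n = 2), a change of 0.377 (SE 0.0907, limma adjusted p 0.0351). 28S-Gm2817 changed by 0.154, and 28S-Um4276 (3574 and 3424) by 0.0743, from 0.901 ± 0.00713 (n = 3) to 0.975 ± 0.00436 (n = 2). 28S-Cm3820 (3101 and 2989) changed by -0.205, from 0.916 ± 0.0705 (n = 3) to 0.712 ± 0.0598 (n = 2). 18S-Am1637 (1702 and 1656) changed by -0.136, from 0.922 ± 0.0164 (n = 3) to 0.787 ± 0.0272 (n = 2), and 18S-Um287 by -0.0648. The limma adjusted p was 0.0370 for 18S-Am1637 and 0.0351 for the other 5. At each of the 6 sites both adult libraries lay outside the range of the 3 protruding-mouth libraries, as they did at uncalled sites such as 18S-Am1678. The 6 sites were picked by this comparison, so this adds no support. With barcode-corrected scores 8 sites passed, the same 6 with 18S-Gm436 and 18S-Am1678. The limma adjusted p of these added sites with uncorrected scores was 0.941 and 0.464. The count was 0 without 32-cell library 3, protruding-mouth library 1, protruding-mouth library 3, adult library A or adult library B, 1 without egg library 2 and 2 without protruding-mouth library 2. With barcode as a block it was 3, all higher, of which 1, 5.8S-Um14, was shared. With the logit it was 4, with 2 flanking positions 2 and with barcode-corrected scores on the logit scale 5, in each with 0 lower.

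The fixed lists of sites gave few matches by number. Of 6 sites known as partial in human or mouse, 2 were matched. Both sites of the 5.8S list were found by number, and neither of the A-loop list. Sites under another numbering are not found this way, so 0 matches do not show that the A-loop sites are absent: an adjacent U and G, 28S-Um4468 and 28S-Gm4469, are among the 98 sites, seen after the matching and not tested as a list.

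In adult tail against egg 18S-Cm1272 differed by 0.174 (SE 0.127, limma adjusted p 0.633) and 28S-Gm4593 by -0.0190 (SE 0.0420, limma adjusted p 0.851). Their mean absolute change was 0.0966, against 0.0688 at the other 96 sites, and was not tested with 2 sites. Adjusted over the list alone, 0 of these 2 passed in any of the 5 comparisons of stages. In the 5.8S list, 1 of 2 passed adjusted over the list alone in adult tail against protruding-mouth (5.8S-Um14, limma adjusted p 0.00358) and 1 of 2 in adult tail against egg (5.8S-Um14, change 0.309, limma adjusted p 0.0127, against 0.125 over all sites). 5.8S-Gm75 passed in neither. Of the A-loop list 0 of 2 were matched.

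Positions that the authors do not list show the background of the assay. Its median was low, its upper tail reached into the range of partial scores, and it varied between libraries of a stage. Few unlisted positions reached the level of the listed sites.

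The median over unlisted positions of the stage mean was 0.117 in egg, 0.132 at 32-cell, 0.185 at 12-somite, 0.143 at protruding-mouth and 0.0931 in adult tail. Of single libraries the third of 12-somite had the highest median, 0.213, and the first, with 0.0786, lay below the 3 of 32-cell, with 0.0803 to 0.103. A score of at least 0.75 in every library of the stage was seen at 3, 20, 17, 1 and 9 unlisted positions in these stages, against 86, 82, 82, 84 and 89 of the 98 listed sites. Of 5561 unlisted positions paired between early and late rRNA, 0 reached 0.75 in all 14 libraries. The highest mean over the libraries, 0.842, was at G of position 137 of early 5.8S rRNA, which reached 0.75 in 10 of 14 libraries.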

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

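Chosen after seeing the data were the barcode-corrected scores (alone, on the logit scale or with barcode as a block), barcode as a block, 5' read ends only, scores not limited at 0, the sites without corrections, the replicate block within the 3 stages from 32-cell to protruding-mouth, and leaving out a library of a stage outside the comparison. The cause of these shifts was not tested. A lone adult library was assumed to vary like the others.

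In adult tail against egg, 0 of the 3 called sites reversed under 29 alternatives, some repeating the main fit. 18S-Um287 passed in all 29 (adjusted p 0.000378 to 0.0230), 28S-Cm3916 in 28 (6.42e-06 to 0.0961, the highest in the quasi-binomial model) and 28S-Gm2817 in 25 (0.00165 to 0.232). The count was 6 with the logit, 5 with the 2 stages alone, 5 with barcode-corrected scores and 8 with these on the logit scale, and ran from 2 to 4 without each library in turn.

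Over all 5 stages the count of 3 became 7 with the logit, 6 with barcode-corrected scores and 10 with these on the logit scale. It was 0 with 4 stages, and the replicate block, fitted on the same 4 stages, also gave 0, while 5' read ends only, on these stages, gave 3, of which 1 was shared. Without each library in turn it ran from 0 to 4, with 0 without adult library A or adult library B. The replicate block changed no call, with 0 sites in the 3 comparisons up to protruding-mouth, and 0 within the 3 stages from 32-cell on, whose numbers pair. In 32-cell against egg 0 of 3 same-numbered pairs had a correlation over 0.1, and the 2 pairs sharing a barcode had 0.568 and 0.443.

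In adult tail against protruding-mouth the count of 6 became 0 with trend and robust on, 0 with libraries centred, 0 with the 2 stages alone and 0 in the quasi-binomial model. It was 4 with the logit, 2 with 2 flanking positions, 3 with barcode as a block, 1 with barcode-corrected scores and this block and 5 with these scores on the logit scale, each with 0 lower. Without each library in turn it ran from 0 to 7, with 0 without 32-cell library 3, protruding-mouth library 1 or 3, or adult library A or B, 1 without egg library 2 and 2 without protruding-mouth library 2. The 6 sites passed in 14 to 20 of 31 alternatives, and 0 reversed. Like the 29 above, these 31 count repeats and overstate stability.

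In 32-cell against egg, 1 site passed with the logit, 1 with barcode-corrected scores on the logit scale (28S-Cm3916 in both) and 1 with barcode-corrected scores and barcode as a block (18S-Cm346). Without each library in turn the count ran from 0 to 1, with 1 without 32-cell library 1 or 12-somite library 3. In 12-somite against 32-cell, 1 site passed with the 2 stages alone, 1 with barcode-corrected scores, 1 with these on the logit scale (18S-Gm509 in each) and 1 with 5' read ends only (28S-Gm1303). In protruding-mouth against 12-somite the count was 0 under every alternative.

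With class limits of 0.8 and 0.2 the egg had 8 partial sites and 1 weak site, and protruding-mouth 0 weak sites. With 2 flanking positions 32-cell had 1 weak site and protruding-mouth 0. Without each library in turn the egg had 4 to 7 partial and 1 to 2 weak sites, 32-cell 0 to 1 weak and protruding-mouth 0 to 1 weak.

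Computing the score from the counts, no coverage minimum and setting scores below 0 to 0 moved nothing and say nothing about stability. Not limiting scores at 0 changed no count. A coverage minimum of 50 left out 3 sites.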

Other observations

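The test of libraries with the same barcode in 5' read ends was chosen before its result was seen. The other tests, of 28S-Cm3916, of the sites with wide ranges, of sequence differences near sites and of other splits of the libraries, were chosen only after the results they concern were seen.

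28S-Cm3916 rose from 0.0193 in egg to 0.901 in adult tail. A switch of reference as the whole cause is argued against by the difference of 12-somite minus egg, both on the early rRNA, which was 0.410 (SE 0.109). 3' read ends as the source are argued against by the difference of protruding-mouth minus egg in 5' ends alone, 0.730 (SE 0.105), and low depth by a lowest flanking mean of 523.1 read ends. Barcode as the whole cause is argued against by the differences with barcode as a block, 0.405 (SE 0.0729) for 32-cell minus egg and 0.532 (SE 0.110) for adult tail minus 12-somite. The difference for 32-cell minus egg rests on egg libraries 1 and 2 against 32-cell libraries 2 and 3, which share barcodes. Its SE borrows from the other sites. In that fit limma called 0 of 98 sites, with a smallest adjusted p of 0.216, so it is weak evidence. The sequence difference between early and late rRNA near this site stays open, and a change in methylation during development may also account for the rise, as an untested hypothesis. In adult tail, age and body part cannot be told apart.

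Of the 10 sites whose stage means span at least 0.2 from egg to protruding-mouth, 9 were compared in 5' ends alone, as 3' read ends, which the barcode correction leaves out, could widen the range; at 5.8S-Um8 the 5' score equals the score, so the test is void there. A range under 0.1 remained at 4 of the 9 (18S-Cm462, 28S-Um3904, 28S-Um4272 and 28S-Gm3923) and one of at least 0.2 at 3, of which 28S-Cm3916 (0.730 against 0.714 in the score) and 18S-Gm436 (0.256 against 0.225) were no narrower, so no single reading holds for the 9 as a set. From egg to protruding-mouth, libraries of different stages with the same barcode deviated together in the score. The mean r was 0.524 over 5 pairs across sites, which are not independent replicates (exact permutation p 0.0278). In 5' ends the mean r was -0.00566 (exact permutation p 0.472). Adult libraries share barcodes with 12-somite and protruding-mouth libraries but were not among these pairs. Number and barcode cannot be told apart in 3 of the 5 pairs, which share both. The other same-barcode pairs set egg libraries 1 and 2 with 32-cell libraries 2 and 3. They lie in the order of egg libraries chosen after the correlations were seen, in which pairs with different barcodes also had r over 0.1. Barcode and that order cannot be told apart there. Of pairs with different barcodes, egg library 3 with protruding-mouth library 1 had 0.637 and egg library 1 with protruding-mouth library 2 had 0.579. The pair of 32-cell library 2 with 12-somite library 2 had 0.565. The remaining pairs with different barcodes reached at most 0.401, below the lowest same-barcode pair, 0.443. Of 36 pairings compared in the score, the real one had the highest mean r, and the next had 0.417. At 28S-Gm3923 the authors' means were 0.771, 0.536 and 0.639, uncorrected, and 0.930 at protruding-mouth, corrected, while the 5' means lay between 0.946 and 0.974.

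Changes were larger on average, through 2 sites, at the 15 sites with a sequence difference between early and late rRNA within 6 positions: the mean absolute change in adult tail against egg was 0.142, against 0.0563 at the other 83 sites (permutation p 0.0185). On 1 reference, 12-somite against egg, it was 0.0898 against 0.0439 (permutation p 0.0280), while it was 0.0467 against 0.0334 where the reference switches, from 12-somite to protruding-mouth (permutation p 0.372), and the permutation p was 0.860 from there to adult tail. These are among 12 tests computed, and the Benjamini-Hochberg value of the first 2 was 0.168; how to read them was settled after both p-values were seen. These 2 rest on few sites, since without 28S-Cm3916 the permutation p was 0.186 and 0.230, and without 28S-Am4560 as well 0.616 and 0.841, with means turned round, 0.0460 against 0.0563 and 0.0404 against 0.0439. Whether such differences could affect the scores therefore cannot be told apart from the change at these 2 sites.

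For all 5 stages, 1 of 100 splits of the libraries, the real one, gave as many as 3 sites, and the highest of the others 2, so a random grouping is excluded as the source of this count only as far as the libraries are exchangeable. Same-numbered libraries of 32-cell, 12-somite and protruding-mouth deviate together, and so do libraries with the same barcode from egg to protruding-mouth. The count was also 0 with the 4 stages without adult tail. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and a real count of 0 is reached by every split, so these say nothing about the count. All 10 gave at least the real count of 0 in 32-cell against egg (highest other 1), 10 in 12-somite against 32-cell (highest other 3) and 10 in protruding-mouth against 12-somite (highest other 1). The split with 3 sites set 32-cell libraries 1 and 3 with 12-somite library 1, and why it gave more was not tested. It kept 2 of 3 same-numbered pairs together, but the other 5 splits that did so gave at most 1. Of the splits that part all 3 pairs, as the real one does, the other 3 gave at most 0 in 12-somite against 32-cell and 1 in protruding-mouth against 12-somite.

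Some sites with wide ranges were not called by limma with uncorrected scores and all 14 libraries, and are named here after their values were seen. 28S-Am4560 was called in adult tail against egg with the 2 stages alone, 18S-Cm346 and 5.8S-Um8 in adult tail against protruding-mouth with the logit, among other alternatives. 28S-Am4560 had a stage mean of 0.245 ± 0.137 (SD, n = 3) in egg and 0.896 ± 0.0433 (n = 2) in adult tail. Its 5' mean in egg was 0.630 ± 0.112 (n = 3). 18S-Cm346 had 0.843 ± 0.0501 (n = 3) in egg, 0.480 ± 0.231 (n = 3) at 32-cell and 0.922 ± 0.00295 (n = 2) in adult tail. Its 5' means were 0.966 ± 0.0283 (n = 3) in egg and 0.964 ± 0.00836 (n = 3) at 32-cell. They were 0.956 ± 0.0185 (n = 3) at 12-somite and 0.769 ± 0.140 (n = 3) at protruding-mouth. 5.8S-Um8 had 0.553 ± 0.211 (n = 3) at protruding-mouth and 0.976 ± 0.00305 (n = 2) in adult tail. In 4 stages, 36 of 1176 library values, at 12 sites, had a 5' score at least 0.2 above the score without any correction by the authors, and 12 had one at least 0.2 below. The late rRNA of the protruding-mouth and adult sheets differ at position 1270 of 18S.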
